A study of Homo sapiens with 9 samples.

How the data were processed

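RNA from LAPC4 cells, a human prostate cancer line, was measured on Illumina expression arrays in 9 samples, 3 each of vehicle (ethanol) control, 1 µM 5α-Abi and 0.1 nM dihydrotestosterone (DHT). Per the labels' protocols, cells were kept without serum and phenol red for 2 days and then treated for 48 h. Groups and replicate numbers came from the sample labels. Nothing in the labels says that the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

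The deposited value table holds linear intensity, 1 row per gene symbol. Per the submitters' processing notes the tool was GenomeStudio, with no version given. The deposited intensities were background-subtracted, since 25.1% to 28.4% of them lie below 0 on each array, and they were scaled so that each array's mean lay between 199.9 and 201.9. The method of scaling is not given in the sources used here. A second deposited table holds 36 columns of per-array values named by slide and position only. These names match no sample label, so the columns were used in no step. Only its annotation text (accession, symbol, chromosome and synonyms, deposited with the values) was used. The column names place 3 arrays on one slide and 6 on another, without saying which samples these were. Slide can therefore coincide with a group and could not be tested.

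The design fixed before the data were examined called for a background model based on detection p-values. As those columns could not be matched to samples, the 92 ERCC spike-in control sequences of the value table were used as negative controls in limma's neqc function, which applies a normexp background correction, an offset of 16, quantile normalization and log2. The controls lay at background on every array, with medians from -4.74 to -2.81. A gene was above background on an array where fewer than 0.05 of the controls were as bright, and it was tested if this held on at least 3 of the 9 arrays. Of 34593 genes, 21671 were tested and 12922 were not. The number of arrays limits the precision. The median 95% confidence interval of a log2 fold change was ± 0.30 wide. The offset makes fold changes of dim genes smaller than those of the transcripts. A gene not above background on any array of a group has only a bound there. Its fold is given as "at least", against the higher of its own signal and the lowest signal above background on each of those arrays, as means of normalized log2 values.

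Symbols were brought up to date through the reference table of RefSeq genes. Of the genes, 18928 were matched by accession, 1754 by symbol and 912 by synonym, and 12999 kept the file's name. Tests were run with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, all 9 arrays in 1 fit with a mean per group). The p-values are two-sided and Benjamini-Hochberg adjusted within each comparison, with a threshold of 0.05. Errors of log2 fold changes are standard errors from that fit. Fixed lists of genes (26, each with at least 5 measured members) were tested with camera at a preset correlation of 0.01, adjusted over the 26 lists of a comparison. Of the 501 distinct list members, 25 stand in more than 1 list. A change counted "adjusted over the list alone" uses only the p-values of that list's members.

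The genes named were chosen by a rule fixed before the data were examined. In each comparison it takes the 12 largest rises and 12 largest falls past the threshold whose arrays were fully separated and above background in the higher group, leaving out uncharacterised and Y-linked names. It also takes up to 4 members of each list with the lowest p-values, a fixed set of androgen-related and steroid-metabolism genes, and the genes called with both treatments that had the largest smaller change. Genes named outside the rule are marked as such, and some genes that the rule takes are not reported here.

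The procedure was tested on 20 simulated data sets of 9 arrays made from the real levels and rotated residuals, in which on average 21558 genes passed the filter. In the simulated 5α-Abi against control comparison, 200 genes were changed, drawn only from those above background on all 9 real arrays. Of the real genes, 12813 met this, so the recovery of dimmer genes was not tested. Of genes changed by 2 on the log2 scale of the signal, 90.3% were recovered, with 58.1% of those changed by 1 and 6.42% of those changed by 0.5. The median estimates were 1.67, 0.83 and 0.41, against 1.73, 0.87 and 0.44 computed from the offset. Of all calls, 3.74% were genes that had not been changed, and in 1 of the simulated sets the share reached 27.5%. In the simulated DHT against control comparison, a list of mitosis genes lowered by 0.3 was called in 19 of 20 sets. False gene calls numbered 21 in 1 set and 0 in the other 19, a mean of 1.05. At least 1 of the other 25 lists, none of them changed, was also called in 7 of the 20 sets. Calls of camera at the preset correlation were therefore set beside those with an estimated correlation.

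Comparisons against the same control arrays share chance values. The resemblance of the responses was set beside 100 simulations of unchanged groups against shared controls. The 3 control arrays are too few to give each comparison at least 2 of its own. Alternatives planned before the data were examined covered background correction, normalization, the filter, the arrays fitted, the variance model, array weights, the replicate number as a block, a fold threshold, other list tests and leaving out each array. Those chosen after seeing the data were normexp fitted on all genes, an offset of 50, a background level from the values below 0, and leaving out the most variable array of each group. Slide as a block and a test of every probe were planned and not run, the latter because the table holds 1 row per gene. Figures were drawn with matplotlib.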

Results

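Gene expression was measured in LAPC4, a human prostate cancer cell line, to determine the effect of 5α-Abi on it. 5α-Abi is a 5α-reduced steroidal metabolite of abiraterone, a drug that inhibits the androgen-synthesis enzyme CYP17A1. DHT, the potent natural androgen, served as the reference. Each of the 3 groups (vehicle control, 1 µM 5α-Abi and 0.1 nM DHT, all at 48 h) had 3 arrays. Between 16804 and 21600 genes were above background per array. Across genes, arrays of 1 group correlated with r from 0.986 to 0.994 and arrays of different groups with r from 0.983 to 0.992. The median variance between replicate arrays was 0.0193 in the control, 0.0155 in the 5α-Abi and 0.0327 in the DHT group.

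The comparison of 5α-Abi with control asked which genes changed with the compound. KLK2, a kallikrein protease gene on chromosome 19 that androgens induce, rose by 2.87 ± 0.17 (log2, SE; 7.32-fold; adjusted p = 1.45e-06), from a normalized log2 intensity of 4.85 ± 0.12 to 7.72 ± 0.17 (SD, n = 3). CYP1A1 on chromosome 15, which encodes a xenobiotic-metabolizing cytochrome P450, rose by 3.71 ± 0.18 (13.1-fold; adjusted p = 2.18e-07), from 4.70 ± 0.22 to 8.41 ± 0.27 (SD, n = 3). It was above background on 2 of the 3 control arrays, as was MAOA. Its relatives CYP1B1 and CYP1A2 rose as well. CYP1B1 changed by 1.43 ± 0.16, and CYP1A2, not above background on any control array, was at least 2.34-fold higher (adjusted p = 0.00149). MAOA, the gene of monoamine oxidase A, rose by 1.62 ± 0.18, DDIT4L by 1.58 ± 0.12 and SERPINE2, a secreted protease inhibitor, by 1.44 ± 0.14. GHR, the growth hormone receptor, rose by 1.25 ± 0.18. SERHL2, ZPLD1 and ANKRD29 rose by 1.26, 1.25 and 1.08. CGA, which encodes the common subunit of the glycoprotein hormones, fell by 1.04 (SE 0.16), and OGFRL1 fell by 0.74 (SE 0.13).

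Of the 35 measured members of the list of androgen-induced genes, 4 rose with 5α-Abi, none fell and 31 did not pass the test. Adjusted over the list alone, 15 rose. The 4 were KLK2, C1orf116 (1.89 ± 0.18), KLK4 (0.84 ± 0.14) and SLC45A3 (0.82 ± 0.15). The list's median was 0.24 (camera adjusted p = 1.95e-13; adjusted p = 0.0114 with an estimated correlation), and 0.14 with median scaling, 0.16 with no filter and 0.12 with an offset of 50. KLK3, which encodes prostate-specific antigen and is a close paralog of KLK2, was at 0.65 ± 0.14 (adjusted p = 0.126), TMPRSS2 at 0.72 ± 0.14 (adjusted p = 0.0750) and FKBP5 at 0.67 ± 0.12 (adjusted p = 0.0589). These 3 did not pass the test over all genes and were among the 15 that rose adjusted over the list alone.

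The list of aryl hydrocarbon receptor and pregnane X receptor targets had 7 measured members. CYP1A1, CYP1A2 and CYP1B1 rose and 4 members did not pass the test. ALDH3A1 was at 0.42 ± 0.20 (adjusted p = 0.580). The list's median was 0.42 (adjusted p = 1.81e-07; adjusted p = 0.0298 with an estimated correlation). It was 0.0052 with no filter, where camera still called the list (adjusted p = 0.00276). The median was 0.11 with the deposited values or with quantile normalization without normexp, and 0.91 with a background threshold of 0.01. Of 13 glucocorticoid receptor targets none passed the test over all genes, and 4 rose adjusted over the list alone, among them FKBP5 and CEBPD (0.53 ± 0.12). FKBP5 also stands in the androgen-induced list. The median was 0.22 (adjusted p = 2.29e-04; adjusted p = 0.0405 with an estimated correlation), and 0.14 with median scaling.

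Among 28 genes of mitosis, 27 had negative changes and none passed the test. The median was -0.22 (adjusted p = 1.88e-07; adjusted p = 0.476 with an estimated correlation). Among 28 genes of DNA replication, 22 were negative and none passed, with a median of -0.11 (adjusted p = 0.00258; adjusted p = 0.476 with an estimated correlation), and -0.20 with median scaling. Of 24 genes of cholesterol synthesis and uptake, none passed over all genes and 3 fell adjusted over the list alone (SQLE, CYP51A1 and ACAT2). The median was -0.08 (adjusted p = 0.00393; adjusted p = 0.476 with an estimated correlation), -0.19 with median scaling and -0.13 without control replicate 2. SQLE, which encodes squalene epoxidase, was at -0.57 ± 0.14.

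Over all genes, 30 changed with 5α-Abi (28 up, 2 down), 17 of them at least 2-fold, and the arrays of all 30 were fully separated. Full separation held for 18.9% of genes, where chance gives 10%. At an unadjusted level of 0.05 there were 1887 genes, against 1084 by chance. In simulated sets of this comparison, 3.74% of all calls were genes that had not been changed, and 27.5% in the set with the highest share. Those sets held 200 changed genes, so the shares do not give the number of false calls among the 30. Leaving out a control or a 5α-Abi array brought the count to between 9 and 13, and quantile normalization without normexp gave 16 up and 5 down, of which 9 were among the 30.

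**Figure D1:**
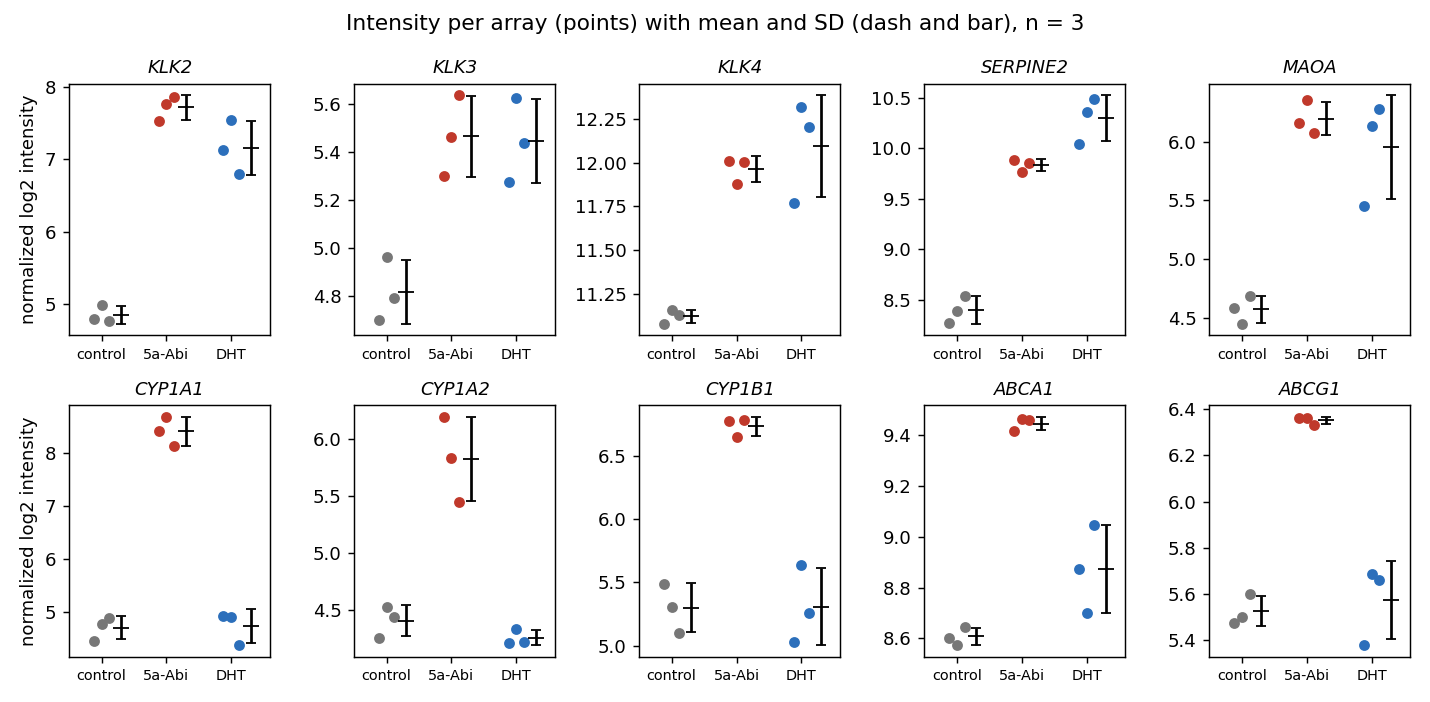
Normalized log2 intensity of 10 genes on each array, by group. Points are the 3 arrays of a group, and the dash and bar are their mean and SD. CYP1A1, CYP1A2, CYP1B1, ABCA1 and ABCG1 separate the 5α-Abi arrays from the other 6, while KLK2, KLK4, SERPINE2 and MAOA are higher with both treatments. For ABCA1 and ABCG1 the 5α-Abi minus DHT difference did not pass the test.

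DHT was compared with the same control arrays to show the response to a reference androgen. SERPINE2 rose by 1.90 ± 0.14 (3.73-fold; adjusted p = 2.53e-05) and KLK2 by 2.31 ± 0.17 (4.95-fold; adjusted p = 2.53e-05), to 7.15 ± 0.38 (SD, n = 3). SERHL2 rose by 1.55 ± 0.22, DDIT4L by 1.39 ± 0.12 and MAOA by 1.38 ± 0.18. HES6, a gene of the Hairy and Enhancer of Split family, rose by 1.16 ± 0.13, HOMER2 by 1.15 ± 0.16, IGSF21 by 1.06 ± 0.15, and KIF5C, a kinesin gene, by 0.84 ± 0.12. MAS1 fell by 0.99 (SE 0.14) and RNASEH2B, which encodes a subunit of ribonuclease H2, fell by 0.82 (SE 0.13).

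Of the 35 measured androgen-induced genes, 3 rose with DHT and 32 did not pass the test. Adjusted over the list alone, 11 rose. The 3 were KLK2, C1orf116 (1.62 ± 0.18) and KLK4 (0.97 ± 0.14). SLC45A3 was at 0.79 ± 0.15 (adjusted p = 0.0858) and KLK3 at 0.63 ± 0.14 (adjusted p = 0.132). The list's median was 0.22 (adjusted p = 3.36e-08; adjusted p = 0.0421 with an estimated correlation), and 0.14 with no filter. None of the 7 aryl hydrocarbon receptor and pregnane X receptor targets passed the test (adjusted p of the list = 0.614). Mitosis genes had a median of -0.21, with 27 of 28 negative and none past the test (adjusted p = 8.96e-07; adjusted p = 0.517 with an estimated correlation). DNA replication genes had a median of -0.12 (adjusted p = 0.00549; adjusted p = 0.660 with an estimated correlation), and PCNA and TYMS fell adjusted over the list alone. Leaving out DHT replicate 2 ended the calls of both lists, with medians of -0.09 and -0.05. With the deposited values these medians were -0.13 and -0.01, and without DHT replicate 3 that of mitosis was -0.34. Glucocorticoid receptor targets had a median of 0.16 (adjusted p = 0.00952; adjusted p = 0.196 with an estimated correlation), with 3 of 13 higher adjusted over the list alone, and its call ended without control replicate 2. Its median was 0.31 with the deposited values and 0.07 without DHT replicate 3.

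Over all genes, 15 changed with DHT (13 up, 2 down), 9 of them at least 2-fold. In simulated sets of this comparison, 1 of 20 gave 21 false calls, more than this count, and the others gave none. At an unadjusted level of 0.05 there were 2465 genes, and 14.8% of genes were fully separated, against 10% by chance. The split moved with the scaling, to 14 up and 10 down with median scaling, 9 up and 3 down with quantile normalization without normexp, and 6 up and 0 down with the deposited values. Leaving out a control array brought the count to 5 or 6.

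All 13 genes that rose with DHT also rose with 5α-Abi. By the smaller of their changes, KLK2 and C1orf116 came first, followed by SERPINE2, DDIT4L, MAOA, SERHL2 and HOMER2. No gene fell in both comparisons, and none was called in opposite directions. Independent lists would share 0.017 genes, and unchanged groups simulated against shared controls shared 0, which does not measure what the controls bring to the 13, since unchanged groups give few calls. The log2 fold changes correlated across genes with r = 0.57, where simulated unchanged groups gave 0.45 with an SD of 0.35. Genes are not independent replicates. The covariance was 0.0229, against 0.0131 simulated, a difference of 0.0098 that lies within the simulated SD of 0.0147. Part of the overlap and of the correlation may come from the shared controls. Of the changes, 69.6% had the same sign in both comparisons, against 66.1% simulated. The count was 4 when any 1 control array was left out and 7 when any 1 of the 5α-Abi arrays was.

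**Figure D2:**
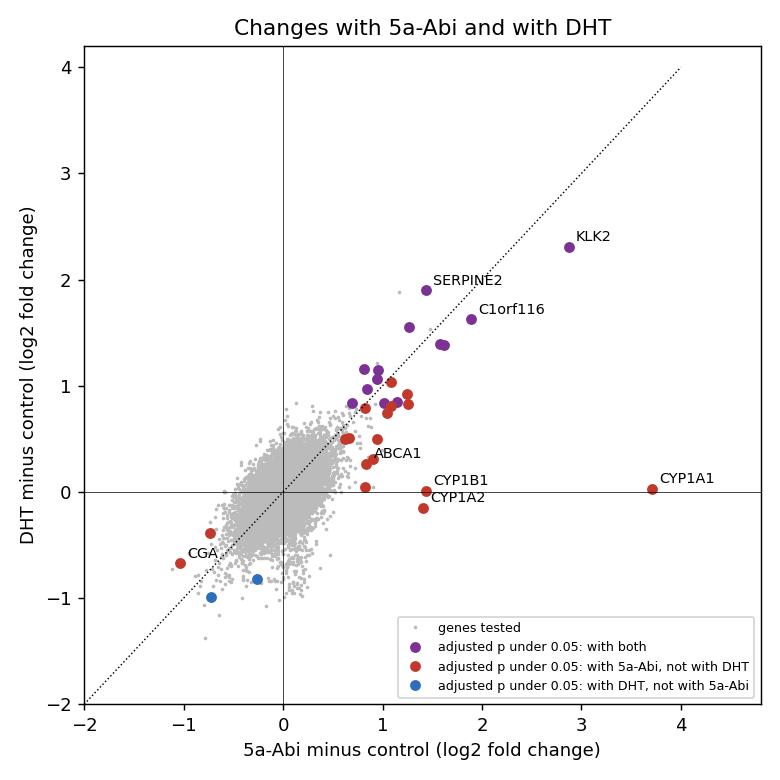
Log2 fold change against control with 5α-Abi (horizontal) and with DHT (vertical) for each of the 21671 genes tested, with the line of equal change dotted. Filled circles are genes past the threshold in both comparisons or in 1 of them. KLK2 lies at 2.87 and 2.31, and CYP1A1 at 3.71 and 0.03.

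The compounds were compared directly, at doses that differed (1 µM against 0.1 nM) and at the same time. Only CYP1A1, CYP1A2 and CYP1B1 passed the test, all higher with 5α-Abi. CYP1A1 was higher by 3.68 ± 0.18 (12.8-fold; adjusted p = 2.43e-07), with 8.41 ± 0.27 against 4.73 ± 0.32 (SD, n = 3). It was above background on 2 of the 3 DHT arrays. CYP1B1 was higher by 1.42 ± 0.16 (adjusted p = 0.00239), and CYP1A2, not above background on any DHT array, was at least 2.33-fold higher (adjusted p = 0.00202). On the DHT arrays CYP1A1 and CYP1B1 differed from control by 0.03 and 0.01. At an unadjusted level of 0.05 there were 1657 genes, and 12.3% of genes were fully separated, against 10% by chance. With the deposited values (1 up, 2 down), or with quantile normalization without normexp (1 up, 1 down), CYP1A2 and CYP1B1 no longer passed, at differences of 1.16 and 1.91 with the deposited values and 1.19 and 2.05 with quantile normalization without normexp.

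No androgen-induced gene passed the test for a difference between the compounds. The intervals of the differences show what the arrays could exclude on the normalized scale. KLK3 was dim (normalized log2 intensity 5.27 to 5.64 on the treated arrays), and the offset makes differences of such genes smaller than those of the transcripts. For KLK2 the 5α-Abi minus DHT difference was 0.56 (95% interval 0.20 to 0.93; adjusted p = 0.427), for KLK3 0.02 (-0.27 to 0.31) and for TMPRSS2 0.14 (-0.15 to 0.44). For FKBP5 it was 0.17 (-0.10 to 0.43). SERPINE2 was lower with 5α-Abi by an estimate that did not pass the test, at -0.46 (-0.75 to -0.17; adjusted p = 0.402). Averaged over the 35 androgen-induced genes, the difference between the compounds was 0.08 (95% interval -0.0025 to 0.16), where 5α-Abi minus control was 0.39 and DHT minus control 0.31. The exact two-sided permutation p of this difference was 0.1, the smallest that 3 against 3 arrays allow. The camera adjusted p was 0.0991.

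The list of aryl hydrocarbon receptor and pregnane X receptor targets was higher with 5α-Abi than with DHT (3 of 7 members; adjusted p = 7.01e-10; adjusted p = 0.0262 with an estimated correlation). Its median was 0.35, and 0.02 with no filter, 0.23 with the deposited values and 0.89 with a background threshold of 0.01. NFE2L2, at 0.35 ± 0.14, passed adjusted over the list alone. Against control it was at 0.10 with 5α-Abi and at -0.25 with DHT. Of the 24 genes of cholesterol synthesis and uptake, 21 were lower with 5α-Abi than with DHT, none past the test over all genes. The median was -0.24 (adjusted p = 5.91e-07; adjusted p = 0.275 with an estimated correlation), and -0.14 without DHT replicate 2. Adjusted over the list alone, 6 were lower, among them MVD (-0.53 ± 0.14), NSDHL (-0.43 ± 0.13) and SQLE (-0.42 ± 0.14), which act in the mevalonate and sterol branches of the pathway. Genes of endoplasmic reticulum folding and the unfolded protein response had a median of -0.12 (adjusted p = 0.0296; adjusted p = 0.275 with an estimated correlation), and immediate early and heat shock genes one of -0.18 (adjusted p = 0.0296; adjusted p = 0.441 with an estimated correlation). The first call also ended without any 1 of the 5α-Abi arrays (adjusted p from 0.0639 to 0.0846) or without DHT replicate 3 (0.0757), and the second without 5α-Abi replicate 1 (0.0846) or 2 (0.0836) or DHT replicate 2 (0.419). The first median was -0.20 with the deposited values, and the second was -0.27 without DHT replicate 1 and -0.08 without DHT replicate 2. Mitosis and DNA replication genes had medians of 0.01 and 0.00 and were not called.

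**Figure D3:**
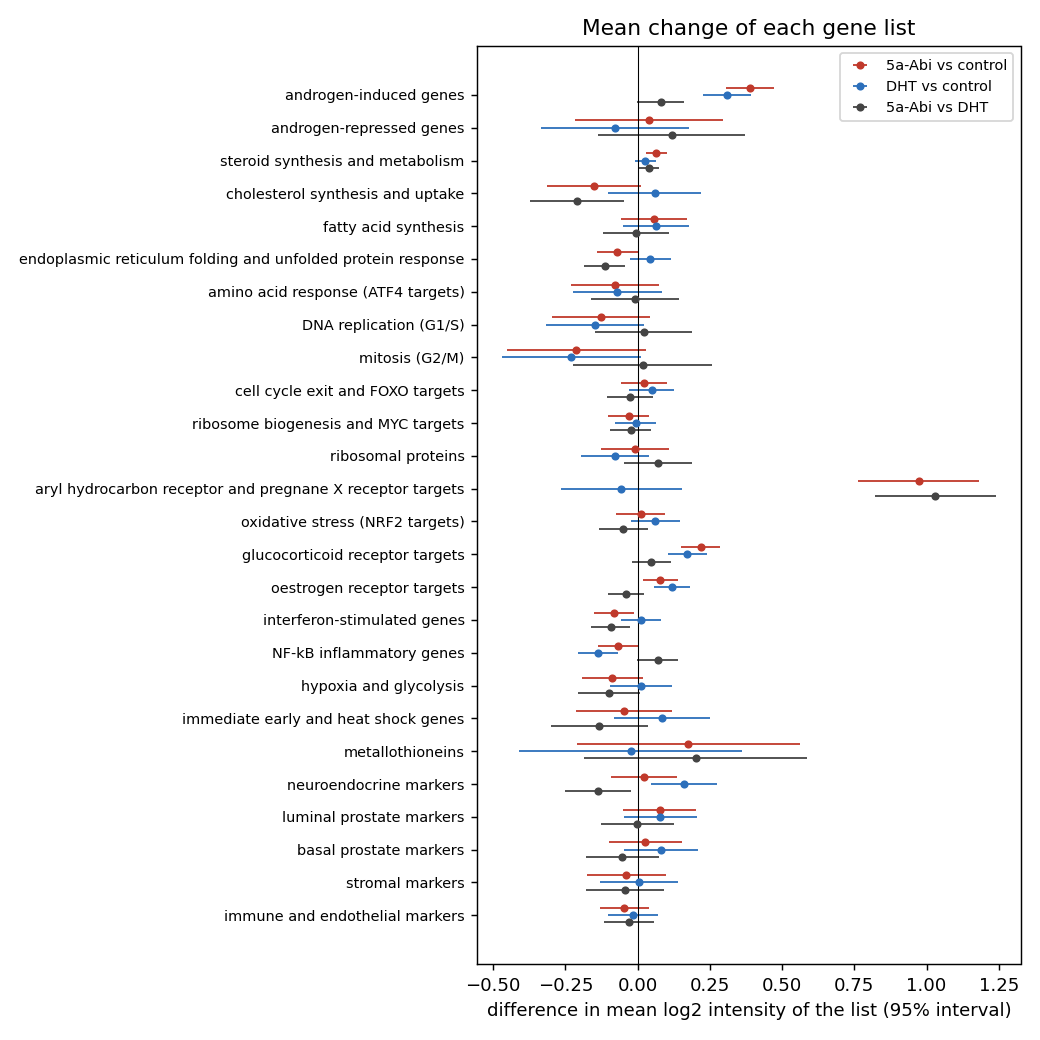
Difference in the mean log2 intensity of each of the 26 gene lists, with its 95% interval from the spread over the 9 arrays, for 3 comparisons. The androgen-induced list lies at 0.39 and 0.31 against control and at 0.08 between the compounds, and the aryl hydrocarbon receptor and pregnane X receptor list at 1.03 between them.

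Enzymes of steroid metabolism were also examined. SRD5A1, a steroid 5α-reductase gene, was at -0.08 ± 0.17 with 5α-Abi and at 0.08 ± 0.17 with DHT. UGT2B15 and UGT2B17, near-identical paralogs that a probe may not tell apart and whose products glucuronidate androgens, were at 0.78 ± 0.18 and 0.62 ± 0.18 with 5α-Abi. Adjusted over the list of androgen-repressed genes alone, both rose with 5α-Abi, opposite to the list's name, and neither passed with DHT. By the same adjustment FOLH1 fell with 5α-Abi (-0.55 ± 0.18) and with DHT (-0.69 ± 0.18). HSD3B1 and CYP17A1 were not among the genes tested.

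The lists that camera called in no comparison were androgen-repressed genes, steroid synthesis and metabolism, fatty acid synthesis, the ATF4 amino acid response, cell cycle exit and FOXO targets, ribosome biogenesis and MYC targets, ribosomal proteins, NRF2 targets, oestrogen receptor targets, interferon-stimulated genes, NF-kB inflammatory genes, hypoxia and glycolysis, metallothioneins and the neuroendocrine, luminal, basal, stromal, and immune and endothelial markers. With fry, which tests whether a list's genes move one way on balance, the oestrogen receptor targets (median 0.06; adjusted p = 0.0157) and NF-kB inflammatory genes (median -0.18; adjusted p = 0.00723) were called with DHT. Among the lists that camera did not call, medians lay between -0.21 and 0.23 with 5α-Abi, between -0.18 and 0.15 with DHT and between -0.12 and 0.17 for the direct comparison. In 4, 6 and 2 of these lists the median, the mean and the test differed in sign.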

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

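Leaving out the most variable array of each group, the offset of 50, normexp fitted on all genes and the background from values below 0 were chosen after seeing the data. With the deposited values, 5 genes changed with 5α-Abi, 6 with DHT and 3 with both, and 8 lists were called with DHT. Quantile normalization without normexp gave 8 genes shared and 7 lists between the compounds. Median scaling gave 18, 24 and 8 genes. Limma's trended, robust variance gave 50, 55 and 26, and an offset of 50 gave 67, 47 and 21. Array weights gave 88 genes with 5α-Abi. A 2-fold threshold gave 17, 9 and 6, by construction fewer. Only 1 gene, CYP1B1, differed between the compounds when all 9 arrays had to be above background, since CYP1A1 and CYP1A2 were then not tested. Without the most variable array of each group there were 9, 5 and 4 genes, 2 lists with DHT and a correlation of 0.50. With an estimated correlation 3, 1 and 1 lists were called with 5α-Abi, with DHT and between the compounds, and fry called 3, 4 and 1. With DHT fry did not call mitosis and DNA replication but called the oestrogen receptor and NF-kB lists. Leaving out single arrays gave 9 to 37 genes with 5α-Abi, 5 to 17 with DHT, 4 to 12 shared and 2 to 3 between the compounds. The count of 2 arose without any 1 of the 5α-Abi arrays, when CYP1A2 did not pass the filter. It gave 2 to 7 lists with DHT, 2 to 6 between the compounds and correlations of 0.49 to 0.65. Fewer arrays were fitted there, and for the other settings the cause was not tested.

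Of the values for named genes under the alternatives, 199 lost and 42 gained their place past the threshold, 110 changed sign without having passed, and 7261 kept direction and side. No gene or list past the threshold changed direction. CYP1A1, KLK2 and DDIT4L kept their calls with 5α-Abi, and KLK2, SERPINE2 and DDIT4L with DHT, in every setting that tested them. Whether the replicate numbers pair the arrays was not settled. Residuals of same-numbered arrays correlated from -0.10 to 0.16, and those of differently numbered arrays from -0.13 to 0.07. The highest values were of same-numbered arrays (control and DHT replicate 2, 0.16, and control and 5α-Abi replicate 1, 0.13). Same-numbered 5α-Abi and DHT arrays correlated negatively. With the replicate block 21, 21 and 4 genes changed with 5α-Abi, with DHT and between the compounds. Slide as a block and a test of every probe were not run. Dim genes are limited by signal over background, as 12922 genes did not pass the filter.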

Other observations

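The tests of probe cross-reading and of the spread between DHT arrays were chosen after the result was seen, and ABCA1, ABCG1 and the lists of other receptor targets were chosen after the data were seen.

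ABCA1 and ABCG1, which encode cholesterol and lipid efflux transporters, rose with 5α-Abi by 0.84 ± 0.12 and 0.82 ± 0.12 (limma adjusted p = 0.0123 for each). With DHT they were at 0.27 ± 0.12 and 0.05 ± 0.12. The direct differences, 0.57 (adjusted p = 0.328) and 0.78 (adjusted p = 0.0890), did not pass the test. The value that almost all of the 500 genes nearest in mean level stayed below was 0.645 at most. That ABCA1 and ABCG1 lay above it decides nothing, since they were picked from the genes called. Most of those neighbours lay between -0.37 and 0.38 for ABCA1 and between -0.39 and 0.37 for ABCG1. Genes of similar mean level therefore did not shift as a whole. A hypothesis is that liver X receptor targets rose as a class. Of 8 other measured targets, 7 were positive, and their median of 0.19 lay at percentile 99.82 of 10000 random lists matched on level. Genes of the random lists were drawn singly, so the percentile makes no allowance for targets that vary together. None of the 8 passed the test over all genes. Their median with DHT was 0.08, and the 5α-Abi minus DHT median was 0.07 with 5 of 8 positive, so the class was not shown to differ between the compounds. Slide stays open as a technical source, as it could not be tested.

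CYP1A1, CYP1A2 and CYP1B1 were higher with 5α-Abi than with DHT. The doses differed (1 µM against 0.1 nM), so compound and dose cannot be told apart in this difference. The value that almost all of the 500 genes nearest in mean level stayed below was 0.785 at most, and the smallest of the 3 differences was 1.42. That gap decides nothing, since the 3 were picked as the only genes called. Most of those neighbours lay between -0.36 and 0.43 for CYP1A1, -0.41 and 0.41 for CYP1A2, and -0.36 and 0.44 for CYP1B1. This argues only against a shift common to genes of that mean level. The 3 genes differed in level between the groups (CYP1A1 8.41 with 5α-Abi against 4.73 with DHT). Shifts at their levels within each group were not tested. The hypothesis that aryl hydrocarbon receptor targets were higher as a class with 5α-Abi met its criterion, since the median of 6 other targets, 0.14, lay at percentile 98.19 of random lists. Those lists, too, make no allowance for targets that vary together. Of the other targets, TIPARP, ALDH3A1, UGT1A6 and NFE2L2 also belong to the aryl hydrocarbon receptor and pregnane X receptor list. That list had already been called in this comparison, so the percentile is not separate support. Only 3 of the 6 were positive, so the class as a whole is weakly borne out. Against control the median was 0.06 with 5α-Abi (4 of 6 positive, TIPARP at -0.23) and 0.03 with DHT. NQO1 was at 0.48 with 5α-Abi and at 0.12 with DHT. Adjusted over the 6 alone, it passed against control (limma adjusted p = 0.00537) and between the compounds (0.36; limma adjusted p = 0.0456). It did not pass over all genes. NFE2L2, at 0.35 between the compounds, was at 0.10 with 5α-Abi and at -0.25 with DHT. Reading of CYP1A1 transcripts by the CYP1A2 probe may account for part of the pattern, since CYP1A2 was above background on 0 of the 6 control and DHT arrays. Induction of CYP1A2 itself would look alike. CYP1B1 was above background on all 6 of those arrays, which does not show whether the CYP1B1 probe reads CYP1A1 when that is high. Slide stays open here too.

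Fewer genes passed the threshold with DHT (15) than with 5α-Abi (30), but this order depended on the processing. The gap widened when only the 6 arrays compared were fitted (14 against 41), with array weights (13 against 88) and with genes above background on all 9 arrays (15 against 39). It turned round with median scaling (24 against 18), with the trended, robust variance (55 against 50) and with the deposited values (6 against 5), and at an unadjusted level of 0.05 there were more genes with DHT (2465 against 1887). For a smaller androgen response with DHT as an explanation, the mean 5α-Abi minus DHT difference of the androgen-induced genes was 0.0796. Its 95% interval ended at 0.162, below 0.194, which is 0.5 of the change of that list with 5α-Abi. This met the criterion against the explanation, but it argues only against a DHT response 0.5 as large or less. A lesser shortfall stays open, since the list rose by 0.39 with 5α-Abi and by 0.31 with DHT, and the interval began at -0.0025. The median residual variance of the DHT arrays was 2.11 times that of the 5α-Abi arrays. This does not decide the counts of 15 and 30, since that fit gave both comparisons the same standard error for each gene, but the fits of 6 arrays and with array weights do not share it, so the spread stays open as an explanation of their wider gap. Doses were not matched, so the counts do not rank the compounds.

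The 6 arrays of a comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In each comparison only 1 split, the real one, gave as many genes. The real counts were 30, 15 and 3, and the highest count of the other splits was 0 in each. Every other split mixes arrays of both groups, so a real difference enters its spread and few calls could arise there. No conclusion is drawn from that 0.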
